A study of Mus musculus with 8 samples.

How the data were processed

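The series holds single-cell RNA sequencing of aortic isografts, pieces of aorta transplanted between mice of 1 strain, here wild-type BALB/c mice, at 2 and 4 weeks after grafting. Per the labels, the adventitia was dissected away from the media and neointima, tissue was digested with papain, and nucleated live cells were sorted before droplet capture with 3' chemistry. The labels leave unclear which of the dissected layers was carried forward. The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalisation. The submitters' notes name Cell Ranger 3.1.0 and the genome build mm10; the annotation release is not given in the sources used here. Each matrix lists 27998 genes. Positions of named genes were taken from a GRCm38 annotation and were used for nothing else.

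The labels list 4 samples at each time point, 8 in all, but each time point has 1 matrix whose barcodes all carry 1 suffix, so that no cell could be assigned to a labelled sample. Each matrix was therefore treated as 1 library and 1 sample. No test between time points was possible, and none was made from cells. Time point and library batch cannot be told apart. Filters, cell type markers, gene lists, the rule for named genes, comparisons and most alternatives were set before the data were examined, and the alternatives added later are named as such in the closing section.

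The matrices held 5011 barcodes together, 2666 at 2 weeks and 2345 at 4 weeks. Cells were kept with at least 500 genes, at most 15% mitochondrial UMIs and no doublet call by Scrublet, run per library on barcodes with at least 200 genes at an expected rate of 0.8% per 1000 barcodes. Scrublet called 2 barcodes in each library, 0.0750% and 0.0853% of barcodes. This was far under the expected rate, so an alternative added later removed the 57 and 44 barcodes with the highest doublet scores. In all, 3284 cells were kept. Total UMIs were 19493107 at 2 weeks and 17442441 at 4 weeks, of which 14130774 and 14341318 were in kept cells.

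Kept cells of both libraries were clustered together in scanpy 1.11.5 (Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, figures with matplotlib 3.10.9). Genes seen in at least 3 cells were scaled to 10000 counts per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.8 with seed 1 gave 18 clusters. A cluster was called X-like after the marker set, among 23, with the highest mean log2 ratio to the median cluster, if at least 3 of its markers reached 2 times that median with at least 10 counts. A cluster with at least 2 cell cycle genes among its 10 leading genes stayed unnamed as dividing. No batch correction was applied.

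Shares of cells are given with exact (Clopper-Pearson) 95% binomial intervals. Expression was compared in classes with at least 100 kept cells in each library and no cluster led by more markers of another class than of its own. The T cell-like class failed the latter, because the leading genes of 1 of its clusters held 1 marker of another class and 0 of its own. Raw counts were summed per library and class and scaled to a total of 1000000 (CPM, counts after scaling), with exact Poisson intervals. Ratios of CPM carry exact conditional (Clopper-Pearson) 95% intervals, and log2 ratios use a prior count of 0.5 in each library. Intervals cover counting error only, not the spread between animals or libraries. A fold against 0 counts is a lower bound taken against 3 counts.

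Of 616 entries written in the 23 cell type marker sets and 27 gene lists together, with genes repeated between sets, 613 were found in the matrices. For each list, the median log2 ratio of members with at least 20 counts was placed among 10000 random lists of the same size, matched on expression in 20 bins. Lists with under 5 such members got no percentile. A percentile of at most 2.5 or at least 97.5 is described as apart from random lists. This describes these libraries and is no test between time points. Named genes are the 8 with the highest and the 8 with the lowest CPM ratio per class among genes that met 4 conditions. They had at least 100 counts together. They had a UMI in at least 10% of cells of the library where they were higher. Their direction was kept under median-of-ratios scaling and after thinning to 2000 UMIs per cell. In at least 1 library their CPM was at least 5% of the highest CPM of any other class in that library, against RNA free in the droplets; the rule as set did not state whether both libraries had to meet this. Mitochondrial, ribosomal protein, haemoglobin, antigen receptor, sex-linked marker and unnamed genes were left out of this ranking. Up to 4 members per described list were also eligible. Dividing cells were those with UMIs of at least 2 of 6 cell cycle genes after thinning to 2000 UMIs.

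The comparison was tested on simulated data with known folds, through the same code. This checks the code and does not show how the intervals or percentiles behave in real cells. There, counts also vary between cells, clusters and libraries, and genes of a list can vary together. Of 100 genes simulated at 2-fold and 100 at 4-fold differences in each compared class, 100% had the right direction. The 95% interval held the true fold for 88 to 96% of them. Of 200 lists with no simulated difference, 4, 10 and 6 lay past the percentile limits in the neutrophil-like, monocyte-like and macrophage-like classes. Alternatives changed the mitochondrial limit, the gene minimum, doublet handling, clustering resolution, seed and variable genes, class assignment, scaling, thinning, weighting of cells or clusters, count minimum and the definition of dividing cells. Barcodes failing the filters were left out of all comparisons. Of the 584 and 438 barcodes with over 50% haemoglobin UMIs, 8 and 9 passed the filters and stayed in.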

Results

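Single-cell RNA was sequenced from control aortic isografts of wild-type BALB/c mice, collected 2 or 4 weeks after grafting. An isograft comes from a genetically matched donor, so it carries the surgery but no mismatch between donor and recipient strains. The labels list 4 samples per time point, which share 1 matrix, so each time point is 1 library without replicates. The 2-week library kept 1723 of 2666 barcodes (64.6%), with a median of 4095 UMIs and 1295 genes per cell. The 4-week library kept 1561 of 2345 barcodes (66.6%), with a median of 5124 UMIs and 1708 genes. Median mitochondrial shares of kept cells were 1.53% and 1.79%, and median ribosomal protein shares were 4.03% and 8.83%. Within classes the ribosomal medians lay closer, at 1.37% and 1.55% in neutrophil-like, 8.54% and 10.4% in monocyte-like and 9.96% and 11.3% in macrophage-like cells. Before filtering, the medians were 4179.5 and 4080 UMIs and 919 and 946 genes.

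The labels state no question beyond the 2 time points, and the shares of cell classes show which cells were recovered at each. Neutrophil-like, monocyte-like and macrophage-like cells made up most of both libraries. Fibroblast-like cells, among the matrix-producing cells of the vessel wall, were 3.37% of kept cells at 2 weeks (58 cells; 95% interval 2.57 to 4.33) and 12.6% at 4 weeks (196 cells; 10.95 to 14.3), a share 3.73-fold higher (2.77 to 5.09). At least 3 of 10 smooth muscle markers occurred in 19 and 38 cells of this class. Endothelial-like cells, which line vessels, were 1.28% (22 cells; 0.802 to 1.93) and 4.16% (65 cells; 3.23 to 5.28), 3.26-fold higher. Monocyte-like cells were 17.1% (15.3 to 18.9) at 2 weeks and 10.8% (9.33 to 12.5) at 4 weeks, a ratio of 0.634 (0.522 to 0.769).

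Neutrophil-like cells were 45.3% of kept cells at 2 weeks (42.9 to 47.7) and 36.3% at 4 weeks (33.9 to 38.7), a ratio of 0.801. Macrophage-like cells held 16.1% (14.4 to 17.9) and 17.2% (15.4 to 19.2), and the interval of their ratio of 1.07 included 1 (0.903 to 1.27). Among immune cells alone, that is outside the fibroblast-like and endothelial-like classes, the macrophage-like ratio was 1.23 (1.03 to 1.46) and the neutrophil-like ratio 0.917 (0.822 to 1.02). T cell-like cells were 7.66% (6.45 to 9.02) and 11.1% (9.57 to 12.7), 1.45-fold higher (1.15 to 1.83). B cell-like cells were 2.09% and 1.41%, and dendritic-like cells 3.13% and 2.31%, with ratio intervals that included 1. NK cell-like cells were 1.22% of both libraries, and plasmacytoid dendritic-like cells 0.638% and 0.641%. A dividing cluster with no class of its own held 2.21% and 2.31%. With each library clustered alone, the T cell-like ratio was 0.753 and the neutrophil-like ratio 1.13, so neither direction held. The minimum of 500 genes weighs on classes by depth, since neutrophil-like cells had medians of 3126 and 3004 UMIs against 15266 and 15957 in macrophage-like cells.

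**Figure D1:**
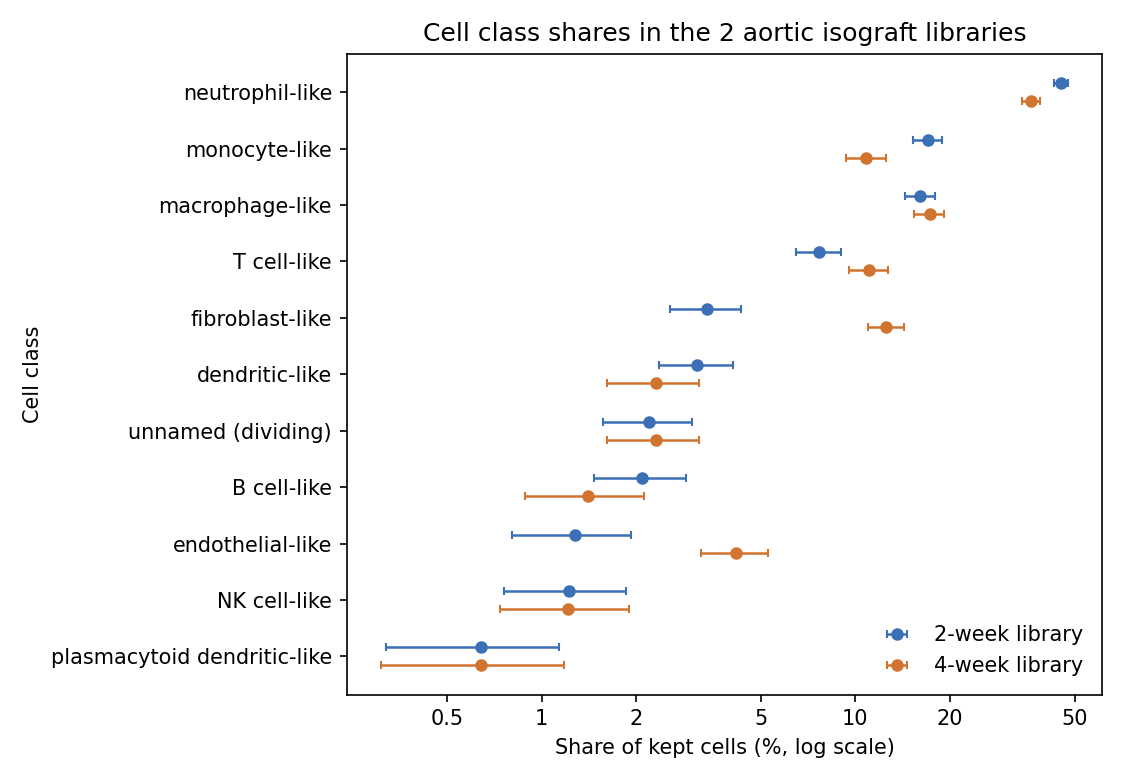
Share of kept cells in each class, in percent on a log scale, for the 2-week (blue) and 4-week (orange) library; points are shares and bars exact 95% binomial intervals. The fibroblast-like share is 3.37% at 2 weeks and 12.6% at 4 weeks, while the macrophage-like intervals overlap.

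Dividing cells were few in both libraries. With every cell thinned to 2000 UMIs, 30 of 1540 cells at 2 weeks (1.95%; 1.32 to 2.77) and 19 of 1407 at 4 weeks (1.35%; 0.815 to 2.10) had UMIs of at least 2 of Mki67, Top2a, Cdk1, Birc5, Ccnb1 and Ube2c. No difference was detectable at this depth. Thinning left out 183 and 154 shallower cells, and without thinning the shares were 3.13% and 3.14%. Over all kept cells, where composition and expression mix, the fibroblast transcript Dcn had 812 CPM at 2 weeks and 3142 at 4 weeks, and Ly6c2, a marker of inflammatory monocytes, had 314 and 171.

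In neutrophil-like cells (780 at 2 weeks with 2492128 UMIs, 566 at 4 weeks with 1932879), genes of the interferon response and MHC class I lists were lower, and Stfa2, Retnlg and Wfdc17 were among the genes that were higher, at 4 weeks in these libraries. Cxcl10, an interferon-induced chemokine, had 831 CPM at 2 weeks and 365 at 4 weeks, 2.27-fold lower (2.09 to 2.48). Stfa2, a cysteine protease inhibitor of the stefin family, had 102 CPM and 654 CPM, 6.39-fold higher (5.58 to 7.34). It was seen in 4.36% of neutrophil-like cells at 2 weeks and 14.1% at 4 weeks, at median depths of 3126 and 3004 UMIs. In macrophage-like cells, with medians of 15266 and 15957 UMIs, it had under 20 counts in both libraries together. Retnlg, a resistin-like protein of neutrophils, had 748 and 2505 CPM, 3.35-fold higher (3.17 to 3.53).

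The other lower neutrophil genes were 2.03- to 2.27-fold lower. Ifit3, an interferon-induced antiviral gene, was 2.11-fold lower (1.78 to 2.52), from 195 CPM at 2 weeks to 92.1 at 4 weeks. Parp9, a partner of interferon signalling, was 2.05-fold lower (1.60 to 2.66), and H2-Q6, a nonclassical MHC class I gene, 2.09-fold lower (1.62 to 2.71). Pcyt1a, the rate-limiting enzyme of phosphatidylcholine synthesis, was 2.27-fold lower (1.58 to 3.32), and the cytoskeletal linker Plec 2.14-fold lower (1.69 to 2.73). Tfeb, a transcription factor of lysosomal genes, was 2.03-fold lower (1.42 to 2.94), and the arrestin-related Arrdc3 2.05-fold lower (1.44 to 2.96). Among the higher genes, the secreted whey acidic proteins Wfdc17 and Wfdc21 were 3.21-fold (3.07 to 3.36) and 2.503-fold (2.36 to 2.66) higher. Mmp8, the neutrophil collagenase, had 98.7 and 244 CPM, 2.47-fold higher (2.11 to 2.89). Ifitm1 and Ifitm6, of the interferon-induced transmembrane family, were 2.29-fold (2.19 to 2.40) and 2.62-fold (2.28 to 3.00) higher, and Ifitm6 was 1.65-fold higher without the 2 cells that held most of its counts. The phosphodiesterase Smpdl3a was 2.73-fold higher (1.94 to 3.87). Stfa2, Retnlg and Wfdc21 also lead 1 cluster of this class, which held 163 of 780 cells at 2 weeks and 153 of 566 at 4 weeks. Wfdc21 leads another as well, with 153 and 99 cells. Stfa2 and H2-Q6 have close paralogs, so how reads were divided within these families is uncertain.

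Of 21 gene lists measured in neutrophil-like cells, 4 were lower and 2 higher than random lists, against 0.525 each way by chance. The interferon response list had 15 of 19 members lower, with a median log2 ratio of −0.46, and Ifit1 had 861 and 441 CPM. Ifit1 is among the leading genes of 1 neutrophil-like cluster, which held 127 cells at 2 weeks and 65 at 4 weeks. The MHC class I list had 13 of 14 members lower (median −0.37), among them H2-Q7 at 182 and 133 CPM and Nlrc5, the transactivator of class I genes, at 29.3 and 15.5. The iron and haem handling list (median −0.43) included the haem-degrading enzyme Hmox1 at 240 and 160 CPM and the iron exporter Slc40a1 at 181 and 116. The lipid-associated macrophage list had 11 of 15 members lower (median −0.29), with the lysosomal protease Ctsb at 1095 and 807 CPM, while Ctsl was higher, at 82.3 and 129. The glycolysis and hypoxia list had 12 of 17 members higher (median 0.12), with Gapdh at 949 and 1286 CPM and Hk2 at 75.4 and 97.3. The modulated smooth muscle list had 6 of 11 members higher (median 0.23), and among them Dcn, which neutrophils should lack, had 22.1 and 42.4 CPM. The fibroblast transcripts Col1a1 (18.1 and 17.6 CPM) and Col3a1 (34.1 and 38.3) differed less. All genes with at least 100 counts had a median log2 ratio of −0.10 in this class, or −0.03 under median-of-ratios scaling. When its 5 clusters were weighted equally, the interferon list had a median of −0.12 and was no longer apart, nor were the MHC class I (−0.22) and glycolysis (0.02) lists. The iron and lipid lists each lost this standing in at least 1 other alternative, and the modulated smooth muscle median turned to −0.15 with a minimum of 100 counts.

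In monocyte-like cells (294 and 169 cells, 3546033 and 1952142 UMIs), genes of the inflammatory, matrix remodelling and lipid-associated lists were lower at 4 weeks in these libraries, and Oas1a was higher. Spp1, the secreted matrix protein osteopontin, had 1405 CPM at 2 weeks and 542 at 4 weeks, 2.59-fold lower (2.42 to 2.77). Arg1, which degrades arginine, was 2.82-fold lower (2.29 to 3.50), and the cytokine Il1a had 272 and 126 CPM, 2.16-fold lower (1.87 to 2.49). Oas1a, an interferon-induced oligoadenylate synthetase of antiviral defence, had 2.54 CPM and 68.6 CPM, 27.0-fold higher (13.8 to 60.4). Its 9 UMIs at 2 weeks lay in 2 cells (0.680% of the class), whereas 26.04% of the class had a UMI at 4 weeks, at median depths of 13188 and 11793 UMIs. Oas1a also belongs to a family of close paralogs.

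The protease inhibitors Timp1 and Slpi were 2.16-fold (1.86 to 2.51) and 2.08-fold (1.98 to 2.20) lower in monocyte-like cells, and Dmkn was 2.499-fold lower (1.83 to 3.47). Ccl5, a chemokine for T cells and monocytes, was 3.33-fold lower (2.90 to 3.84) and 6.52-fold lower without the 2 cells that held most of its counts. The fatty acid carrier Fabp5 was 3.00-fold lower (2.58 to 3.50), or 1.87-fold without the 2 such cells. Among higher genes, Cxcl9, an interferon-induced chemokine, had 119 and 273 CPM, 2.29-fold higher (2.01 to 2.61) and 7.94-fold without the 2 such cells. C1qc, a complement component typical of macrophages, had 66.0 and 139 CPM, 2.11-fold higher (1.77 to 2.53). The acute phase gene Saa3 was 2.63-fold higher (2.53 to 2.74) but 1.25-fold without the 2 such cells. It turned lower with called doublets kept (log2 ratio −1.84), but also with the highest doublet scores removed (−1.605). Only 2 barcodes per library were called, and cells were clustered anew in both runs, so these reversals do not show that doublets carried its counts. The interferon-induced GTPase Iigp1 was 2.19-fold higher (1.74 to 2.76), the chemokine Ccl12 2.12-fold (1.76 to 2.56), Fgd2 2.95-fold (1.96 to 4.49) and Sfi1 2.58-fold (1.80 to 3.71). These 4 were lower with a minimum of 1000 genes per cell, at log2 ratios of −1.55, −1.004, −0.65 and −0.32. In that run cells were clustered anew and the class held only 130 and 56 cells, so it was not the same class. Saa3 and Slpi also lead 1 cluster of this class, which held 109 cells at 2 weeks and 52 at 4 weeks.

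Of 21 lists in monocyte-like cells, 5 were lower and 1 higher than random lists. The list of inflammatory cytokines and NF-kB targets had 16 of 17 members lower, with a median log2 ratio of −0.27. It included Ptgs2, the inducible prostaglandin synthase, at 578 and 358 CPM, the NF-kB inhibitor Tnfaip3 at 474 and 342, and the cytokine Osm at 280 and 211. The matrix remodelling list had 6 of 9 members lower (median −0.32), with the collagenase Mmp13 at 26.8 and 9.73 CPM, while the elastase Mmp12 was higher, at 13.5 and 61.5. Neither met the conditions for ranked genes in this class, and Mmp12 is the first leading gene of a macrophage-like cluster. Whether a few cells carry these values was not examined. The lipid-associated macrophage list had 14 of 19 members lower (median −0.25), with the lipase Lpl at 57.5 and 23.05 CPM. The iron and haem list had 8 of 10 members lower (median −0.26), with Hmox1 at 476 and 242 CPM. The glycolysis and hypoxia list had 15 of 17 members lower (median −0.17), with the growth factor Vegfa at 359 and 200.3 CPM and the glycolytic enzyme Pkm at 1224 and 984. The oxidative phosphorylation list had 13 of 16 members higher (median 0.11), with Sdhb at 133 and 161 CPM. The interferon list had 10 members higher and 11 lower (median −0.02). The fibroblast transcript Dcn had 6.49 and 26.1 CPM in this class, while Col1a1 had 7.33 and 3.59 and Col3a1 15.2 and 19.0. The inflammatory list stayed lower under every alternative run, and each of the other 5 lost its standing in at least 1, such as the lipid list at −0.02 with Leiden resolution 0.4.

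**Figure D2:**
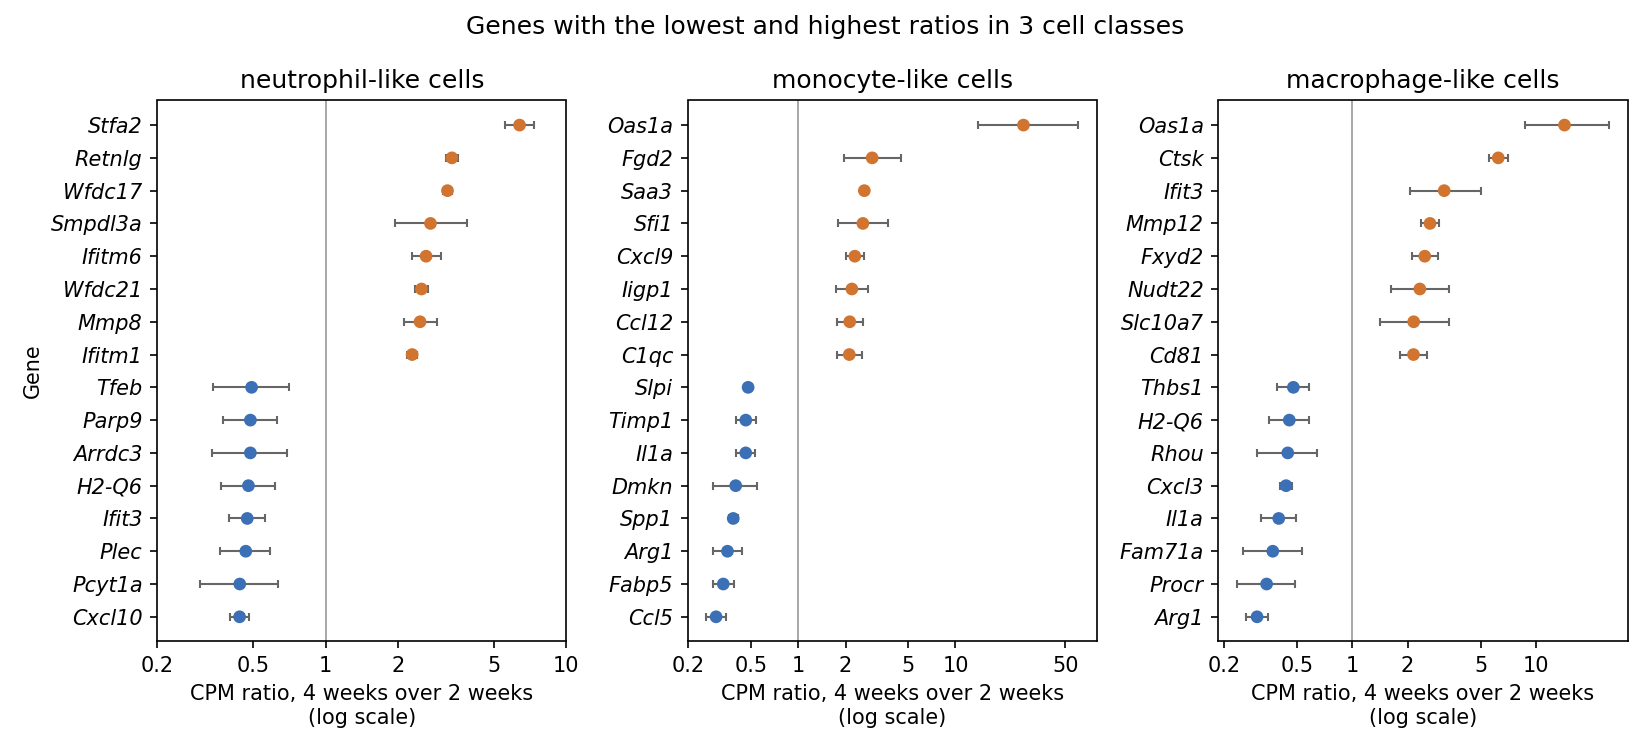
Ratio of CPM at 4 weeks over 2 weeks, on a log scale, for the 16 ranked genes in each of the 3 compared classes; points are ratios, bars exact 95% intervals from counting error, orange higher and blue lower at 4 weeks, and the line marks a ratio of 1. Oas1a stands highest in monocyte-like (27.0) and macrophage-like (14.3) cells, and Stfa2 in neutrophil-like cells (6.39).

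In macrophage-like cells (277 and 269 cells, 4227506 and 4388376 UMIs), genes of the interferon response list and the proteases Ctsk and Mmp12 were higher at 4 weeks in these libraries, and genes of the inflammatory and monocyte-derived lists were lower. Ctsk, a cathepsin that degrades collagen, had 75.0 CPM at 2 weeks and 467 at 4 weeks, 6.23-fold higher (5.53 to 7.03). Mmp12, the macrophage elastase, had 104 and 276 CPM, 2.65-fold higher (2.37 to 2.96). Oas1a had 4.02 and 57.4 CPM, 14.3-fold higher (8.74 to 24.9), with a UMI in 2.89% and 28.3% of the class. Arg1 had 214 and 64.9 CPM, 3.29-fold lower (2.88 to 3.77).

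The other lower macrophage genes included Procr, the protein C receptor, 2.92-fold lower (2.05 to 4.24), and Thbs1, a thrombospondin of the matrix, 2.09-fold lower (1.72 to 2.55). H2-Q6 was 2.20-fold lower (1.71 to 2.85), as in the other compared classes. Fam71a was 2.70-fold lower (1.89 to 3.94), and the small GTPase Rhou 2.24-fold lower (1.55 to 3.28). Il1a was 2.51-fold lower (2.01 to 3.15), and the neutrophil-attracting chemokine Cxcl3 2.29-fold lower (2.13 to 2.46). Both turned at Leiden resolution 0.4, to log2 ratios of 0.13 and 1.85. Among higher genes, Fxyd2, a regulator of the sodium pump, was 2.48-fold higher (2.11 to 2.93), the tetraspanin Cd81 2.15-fold (1.82 to 2.55) and the carrier Slc10a7 2.16-fold (1.42 to 3.36). Ifit3 had 6.62 and 21.0 CPM, 3.17-fold higher (2.05 to 5.02), but a log2 ratio of −0.36 when cells were assigned by marker score. Nudt22 was 2.33-fold higher (1.63 to 3.38) and turned to −0.23 under that assignment. Mmp12 and Arg1 also lead 1 cluster of this class, which held 143 and 127 cells.

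Of 25 lists in macrophage-like cells, 9 were lower and 5 higher than random lists, against 0.625 each way by chance. The interferon response list had 19 of 21 members higher, with a median log2 ratio of 0.41. Gbp2, an interferon-induced GTPase, had 16.8 and 31.9 CPM, while Cxcl10 was lower, at 142 and 68.4. The monocyte-derived macrophage list had 13 of 16 members lower (median −0.55), with Ly6c2 at 49.4 and 23.2 CPM. S100a9 of that list had 181 and 88.9 CPM, and it is abundant in neutrophils. The inflammatory list had 15 of 16 members lower (median −0.32), with the cytokine Il1b at 1068 and 546 CPM and Ptgs2 at 209 and 104. The resident macrophage list had 12 of 15 members lower (median −0.29), with Lyve1 at 21.1 and 8.89 CPM and F13a1 at 348 and 191. The MHC class II list had 9 of 10 members lower (median −0.25), with its transactivator Ciita at 31.0 and 16.4 CPM and H2-Eb1 at 3033 and 2286. The lists of T cell activation (median −0.45) and endothelial adhesion (−0.29, with Vcam1 at 19.6 and 4.79 CPM) hold genes that macrophages share. The iron and haem (−0.22, Hmox1 at 584 and 305 CPM), matrix remodelling (−0.22, Mmp13 at 30.3 and 7.98) and heat shock (−0.20, Hspa8 at 3049 and 2272) lists were also lower.

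The oxidative phosphorylation list had 14 of 16 members higher in macrophage-like cells (median 0.19), with Sdhb at 173 and 219 CPM and Cox6c at 426 and 536. The contractile (median 0.35), endothelial-to-mesenchymal (0.23) and modulated smooth muscle (0.21) lists were higher too, with Vcl at 32.2 and 53.1 CPM and Fn1 at 1657 and 2103. Dcn, which macrophages should lack, had 11.8 and 25.1 CPM in this class, while the fibroblast-like share of cells was 3.73-fold higher. The fibroblast transcripts Col1a1 (10.6 and 10.5 CPM) and Col3a1 (20.6 and 18.9) were not higher, so Dcn does not stand for all fibroblast RNA. The lipid-associated macrophage list was not apart (median 0.05), although Lpl had 255 and 418 CPM and Fabp5 154 and 281. The interferon and monocyte-derived lists kept their direction and standing under every alternative run for lists. Assignment by marker score, which turned Ifit3, was not run for lists. The others lost it in at least 1, and the modulated smooth muscle median turned to −0.21 with a minimum of 100 counts and that of matrix remodelling to 0.08 at Leiden resolution 0.4.

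**Figure D3:**
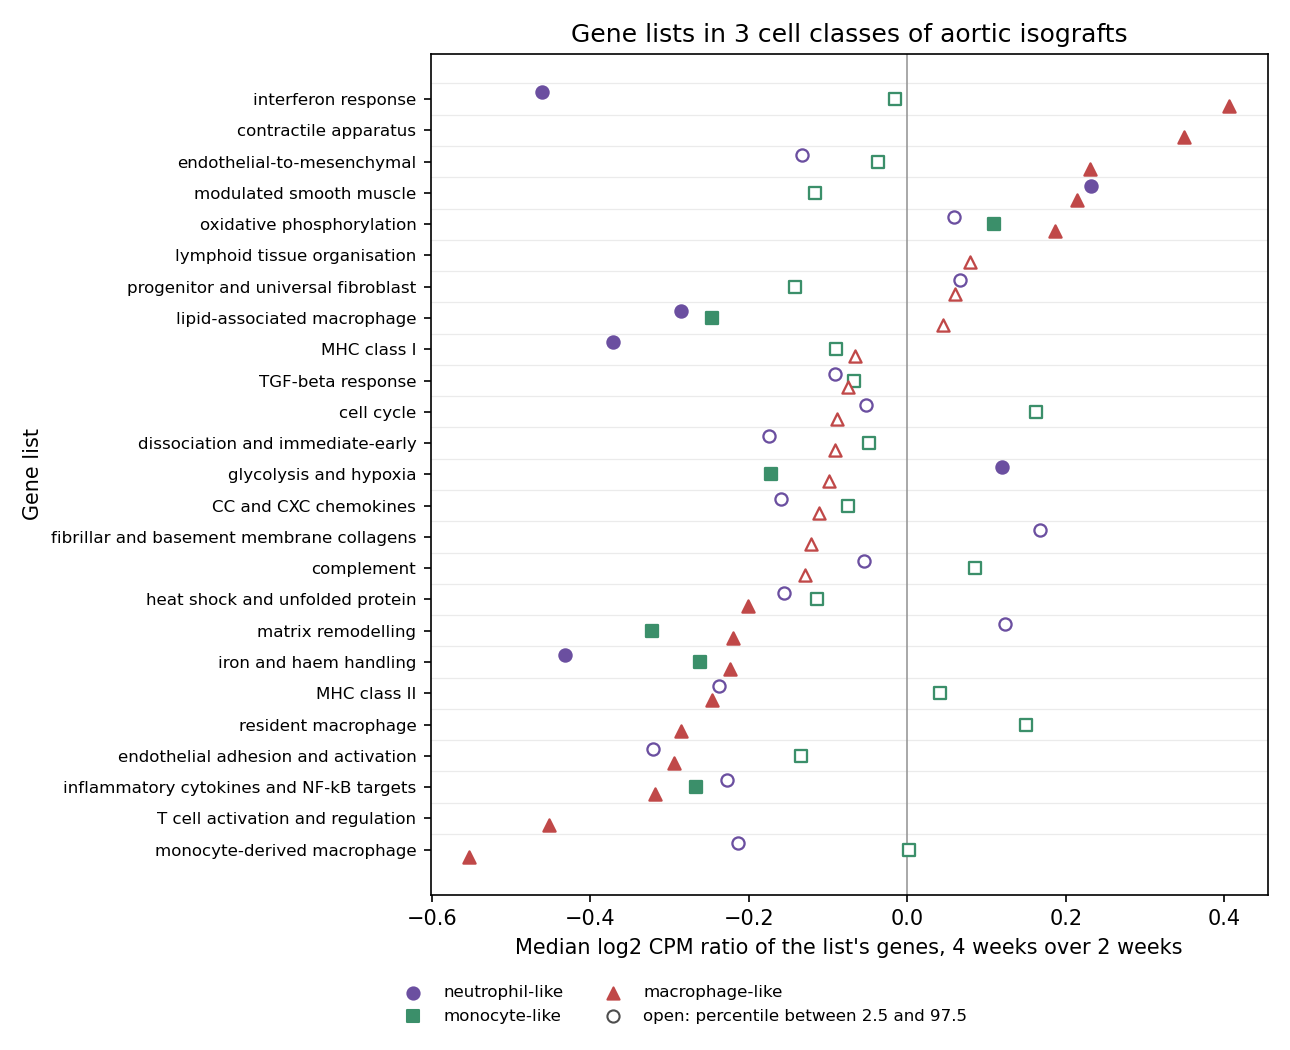
Median log2 ratio of CPM, 4 weeks over 2 weeks, of each gene list in neutrophil-like (purple circles), monocyte-like (green squares) and macrophage-like (red triangles) cells; filled points are apart from random lists and open points lie within the percentile limits. The interferon response list is at −0.46 in neutrophil-like and 0.41 in macrophage-like cells.

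The list of genes that respond to tissue dissociation was not apart in any of the 3 classes, with medians of −0.17, −0.05 and −0.09 in neutrophil-like, monocyte-like and macrophage-like cells. RNA free in the droplets reached all classes. Hbb-bs, a haemoglobin gene of red cells, had a UMI in at least 98.5% of cells of each compared class. S100a8, a neutrophil gene, was seen in 52.3% of macrophage-like cells at 2 weeks and 69.5% at 4 weeks, at 135 and 118 CPM and median depths of 15266 and 15957 UMIs. In GRCm38, Oas1a lies on chromosome 5 from 120896256 to 120907521, Ctsk on chromosome 3 from 95499256 to 95509362, Stfa2 on chromosome 16 from 36403992 to 36408457, Spp1 on chromosome 5 from 104435118 to 104441050 and Cxcl10 on chromosome 5 from 92346638 to 92348889.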

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

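Among the tests given here, equal weights for clusters were chosen only after the results were seen, and no explanation was tested.

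Haemoglobin genes, which are no part of the comparisons, held over 50% of the UMIs in 21.9% of deposited barcodes at 2 weeks (584 barcodes; 20.3 to 23.5) and 18.7% at 4 weeks (438; 17.1 to 20.3). These barcodes had medians of 7944 and 5414.5 UMIs, and 8 and 9 of them passed the filters. The sort kept nucleated cells, and mature red cells have no nucleus in mice.

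Genes of the interferon response list went in opposite directions in 2 classes, with a median log2 ratio of −0.46 in neutrophil-like cells and 0.41 in macrophage-like cells. Ifit3 had 195 and 92.1 CPM at 2 and 4 weeks in the former and 6.62 and 21.0 in the latter, while Cxcl10 was lower at 4 weeks in both. The neutrophil-like cluster led by Ifit3b and Ifit1 held 127 of 780 cells of the class at 2 weeks and 65 of 566 at 4 weeks. With the 5 neutrophil-like clusters weighted equally, the neutrophil-like median was −0.12 and no longer apart from random lists. The glycolysis and hypoxia list also differed, at 0.12 in neutrophil-like cells and −0.17 in monocyte-like cells. Hk2, which starts glycolysis, had 75.4 and 97.3 CPM in neutrophil-like cells, and Vegfa, a hypoxia-induced growth factor, had 359 and 200.3 in monocyte-like cells. Neither median stayed apart from random lists with clusters weighted equally (0.0237 in neutrophil-like and −0.0561 in monocyte-like cells), nor did the monocyte-like one at Leiden resolution 0.4 (−0.0775). The differences between classes were not tested, since each time point is 1 library.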

How the results depend on the processing

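Tests added after seeing the data are equal weights for clusters, removal of the 2 cells with most counts of a gene, and removal of the highest doublet scores. Immune cells alone, and cells outside the neutrophil-like class, were also added later as denominators. The rest were planned. The 2 cells were removed from each library, whatever its number of cells. No paired analysis was possible because the cells carry no replicate number, although the labels number the samples of both time points alike. Depth and cell number limit which classes were compared and leave dividing cells at 30 and 19.

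Fibroblast-like (3.64 to 4.51, and 3.20 among cells outside the neutrophil-like class) and endothelial-like (2.78 to 3.74) share ratios kept their direction under every alternative run for them, as did the monocyte-like ratio, at 0.452 with at least 1000 genes and 0.509 with each library clustered alone. With each library clustered alone, the T cell-like ratio was 0.753 and the neutrophil-like ratio 1.13, both reversed. The neutrophil-like ratio was 0.991 with cells assigned by marker score and 0.917 with immune cells as denominator (0.822 to 1.02). With that denominator the macrophage-like ratio was 1.23 (1.03 to 1.46), an interval that no longer included 1. Dividing cells were 3.13% and 3.14% without thinning, and 6.49% and 4.83% with at least 1 of the genes. Medians of UMIs and genes per cell also moved without a filter.

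Of the values of ranked genes, 453 stayed within their counting interval, 159 moved beyond it in the same direction and 12 reversed. In monocyte-like cells, log2 ratios with at least 1000 genes were −0.65 for Fgd2, −0.32 for Sfi1, −1.55 for Iigp1 and −1.004 for Ccl12. After clustering anew, the class held 130 and 56 cells in that setting. Saa3 was −1.84 with called doublets kept, −2.215 by marker score and −1.605 without the highest doublet scores. In macrophage-like cells, Il1a was 0.13, Cxcl3 1.85 and Nudt22 −0.21 at Leiden resolution 0.4, and Ifit3 −0.36 and Nudt22 −0.23 by marker score.

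Of the values of lists apart from random ones, 181 kept direction and standing, 40 lost the standing and 5 reversed. Those that held in every setting run for lists were interferon (0.25 to 0.64) and monocyte-derived (−0.71 to −0.25) in macrophage-like cells and inflammatory in monocyte-like cells (−0.53 to −0.16). Settings not run for lists include assignment by marker score, other gene minimums or mitochondrial limits, and each library clustered alone. Of the values of other lists, 319 stayed and 31 came to stand apart. The medians that did not hold follow by setting.

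With called doublets kept, macrophage-like medians were 0.33 (contractile), 0.16 (modulated smooth muscle) and 0.19 (endothelial-to-mesenchymal), monocyte-like oxidative phosphorylation 0.0485 and neutrophil-like iron −0.23. Without the 2 cells with most counts, they were 0.35 (contractile) and −0.38 (T cell activation) in macrophage-like cells and −0.29 (lipid) in neutrophil-like cells. Without the highest doublet scores, macrophage-like medians were 0.20 (contractile), 0.16 (modulated smooth muscle), 0.20 (endothelial-to-mesenchymal) and −0.19 (iron), monocyte-like oxidative phosphorylation 0.0305 and neutrophil-like iron −0.28. At a minimum of 100 counts, modulated smooth muscle reversed to −0.21 in macrophage-like and −0.15 in neutrophil-like cells, and neutrophil-like iron was −0.21.

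After thinning, macrophage-like medians were −0.0767 (modulated smooth muscle, reversed), −0.0712 (matrix), −0.12 (MHC class II), −0.18 (resident), −0.16 (endothelial adhesion), −0.11 (heat shock) and −0.22 (iron). Monocyte-like medians were −0.21 (matrix), −0.13 (lipid) and −0.19 (iron), and neutrophil-like ones −0.0360 (modulated smooth muscle, reversed) and −0.0164 (iron). At Leiden resolution 0.4, macrophage-like medians were 0.11 (modulated smooth muscle), 0.0820 (matrix, reversed), −0.0765 (inflammatory), −0.11 (MHC class II), 0.0710 (oxidative phosphorylation) and −0.12 (iron), monocyte-like ones −0.0215 (lipid) and −0.0775 (glycolysis), and neutrophil-like iron −0.24. With clusters weighted equally, monocyte-like medians were −0.11 (lipid), −0.0561 (glycolysis), 0.0820 (oxidative phosphorylation) and −0.15 (iron), and neutrophil-like ones −0.12 (interferon), −0.22 (MHC class I) and 0.0237 (glycolysis). The cause was not tested for any of these.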

Other observations

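The comparison of fibroblast-like cells and all tests of explanations in this part were chosen only after the data were seen. Fibroblast-like cells numbered 58 at 2 weeks and 196 at 4 weeks (1112039 and 3146397 UMIs; medians 18442.5 and 15279.5), under the minimum set for comparison at 2 weeks. Their ranked genes also had to stay at least 1.5-fold apart without the 2 cells with most counts, a condition added after values were seen. The 2 cells were taken from each library, a larger part of 58 cells than of 196. This removal can therefore raise ratios of 4 weeks over 2 weeks by itself, and values without these cells do not settle how stable a ratio is. In these libraries their interferon genes were higher at 4 weeks and their contractile, collagen and elastic fibre genes lower. Of 25 lists, 10 were higher and 4 lower than random lists. Standings changed without the 2 cells with most counts of each gene. Among others, the TGF-beta response (−0.14 to 0.41), endothelial adhesion (0.12 to 0.70) and dissociation (0.08 to 0.24) medians came to stand higher. The cell cycle median (0.14 to −0.36) came to stand lower, and the complement and monocyte-derived lists were no longer apart. The interferon response list had 20 of 20 members higher (median log2 ratio 0.95), and the MHC class I list 12 of 12 (0.37). Cxcl10 was 6.91-fold higher (4.63 to 10.8), Iigp1 3.57-fold (2.79 to 4.63), and the neutrophil-attracting chemokine Cxcl5 11.3-fold (7.54 to 17.8). Spp1 was 4.38-fold higher (3.73 to 5.18), or 10.2-fold without the 2 cells with most counts. It was seen in 20.7% of the class at 2 weeks and 18.4% at 4 weeks, and 1164 of its 1982 counts at 4 weeks lay in 19 cells with Xist and no Y-linked UMIs. Inhba, a subunit of activin, was 10.1-fold higher (5.54 to 20.3), or 3.099-fold without the 2 such cells. The chemokine list had 17 of 21 members higher (0.74), or a median of 0.44 without the 1 and 6 cells that carried at least 3 macrophage markers, and the modulated smooth muscle (0.26) and osteochondrogenic (0.44) lists were higher, with the calcification inhibitor Mgp 2.06-fold higher. The collagen list had 11 of 15 members lower (−0.38), with Col3a1 1.82-fold (1.78 to 1.85) and Col1a1 1.71-fold (1.67 to 1.75) lower, and Cthrc1, a gene of matrix-producing fibroblasts, was 3.46-fold lower (2.97 to 4.04). The elastic fibre list had 14 of 16 members lower (−0.36). The progenitor and universal fibroblast list had 9 of 15 members higher (0.19), with its marker Clec3b 1.95-fold (1.81 to 2.11) and Pi16 1.39-fold (1.32 to 1.46) higher, and the iron and haem list 8 of 8 (0.30). The heat shock list had 11 of 14 members lower (−0.18), and was no longer apart without the 2 cells with most counts of each gene (−0.0142). The contractile apparatus list, of smooth muscle markers, had 11 of 16 members lower (−0.70), or a median of −0.24 without the 2 cells with most counts of each gene. Of that list, Acta2 was 2.92-fold lower (2.76 to 3.097) and Des 4.56-fold (3.21 to 6.53), or 1.47- and 1.31-fold without the 2 such cells. Cells with at least 3 of 10 smooth muscle markers were 19 of 58 in the class at 2 weeks (32.8%; 21.0 to 46.3) and 38 of 196 at 4 weeks (19.4%; 14.1 to 25.6), or 16.7% and 10.3% after thinning. At 2 weeks, 10 cells with Xist and no Y-linked UMIs held 997 of the 2338 Acta2 counts and 152 of the 196 Myh11 counts. In cells with Y-linked UMIs and no Xist, Myh11, a smooth muscle myosin, had 18.7 CPM at 2 weeks and 44.4 at 4 weeks, and Acta2 1435 and 548. The imprinted genes Peg3 and Mest were 5.84- and 5.44-fold lower, or 2.89- and 2.46-fold without the 2 such cells. With cells thinned to 2000 UMIs, which weights cells equally, log2 ratios were 1.104 for Cxcl10 (2.76 unthinned), 2.63 for Iigp1 (1.83), 5.17 for Cxcl5 (3.47), 1.85 for Inhba (3.27), −1.23 for Peg3 (−2.54) and −0.34 for Mest (−2.43). Thinning left 54 cells at 2 weeks, where Inhba (9.89 CPM), Cxcl5 (21.6) and Cxcl10 (22.5) then kept few counts. Their thinned ratios lie near the floor and carry no interval. MHC class II genes had a median of 1.65, but 0.28 without the 1 and 6 cells with macrophage markers. The monocyte-derived list went from 1.04 to −0.31 and the complement list from 0.36 to 0.15 without these cells, while the interferon list was at 0.96. Acta1, a muscle actin, had 1506 of its 1512 UMIs at 2 weeks in 1 cell and 0 at 4 weeks.

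T cell-like cells formed 2 clusters. The smaller held 48 cells at 2 weeks and 69 at 4 weeks, and Rag1, which rearranges antigen receptor genes, was seen in 68.8% (53.7 to 81.3) and 66.7% (54.3 to 77.6) of them. Cd4 and Cd8 transcripts occurred together in 33 and 46 of these cells, and Dntt, which adds nucleotides to receptor joints, in 29 and 42. Such cells are typical of the thymus. Rag1 was seen in 0.128% and 0.707% of neutrophil-like cells, at medians of 3126 and 3004 UMIs against 2040 and 2784 in this cluster. The larger cluster held 84 and 104 cells, led by Cxcr6, a chemokine receptor of tissue T cells. Cxcr6 was seen in 41.7% (31.0 to 52.9) and 61.5% (51.5 to 70.9), and the cytokine Il17a in 9 of 84 cells (10.7%; 5.02 to 19.4) and 20 of 104 (19.2%; 12.2 to 28.1). Il17a was seen in 0% and 0.353% of neutrophil-like cells, and the medians in this cluster were 5353.5 and 5449 UMIs. In B cell-like cells Vpreb3, a gene of developing B cells, was seen in 19 of 36 cells at 2 weeks and 6 of 22 at 4 weeks.

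Xist, the transcript of the inactive X chromosome of female cells, had UMIs in 10 of 58 fibroblast-like cells at 2 weeks and 20 of 196 at 4 weeks, while Y-linked UMIs occurred in every class. Free RNA in the droplets and a female recipient, whose blood cells would carry Xist, are both argued against, since 0.183% of macrophage-like cells and 0.0340% of 2943 immune and dividing cells had an Xist UMI. Of 36 stromal cells with Xist, 2.78% had a UMI of 4 Y-linked genes against 69.2% of the 305 others, which argues against Xist in cells with a Y chromosome. A candidate explanation is that vessel wall cells of female graft donors remained in male recipients: after thinning, 34.5% of 29 fibroblast-like cells with Xist (17.9 to 54.3) had at least 3 of 10 smooth muscle markers, against 7.69% of 156 with Y-linked UMIs (4.04 to 13.1). Within each library these intervals overlapped (40.0% against 5.88% at 2 weeks, 31.6% against 8.20% at 4 weeks), so this stays a hypothesis, found and tested on the same cells, and the labels give no sex of donors or recipients. Other vessel wall cells had Y-linked UMIs. Of 87 endothelial-like cells, 54 had a Y-linked UMI and 6 had Xist. After thinning, at least 3 smooth muscle markers occurred in 12 fibroblast-like cells with Y-linked UMIs and 10 with Xist. The explanation does not by itself cover those Y-linked cells.

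Oas1a was nearly missing from neutrophil-like, monocyte-like, macrophage-like and dendritic-like cells at 2 weeks. Other immune classes were not examined for it. In neutrophil-like cells it had 2 counts at 2 weeks and 63 at 4 weeks (ratio 40.6, interval 10.8 to 343). The paralog Oas1g had the same direction, from few counts. It had 1 and 24 counts in neutrophil-like, 6 and 39 in monocyte-like and 4 and 49 in macrophage-like cells (ratios 30.9, 11.8 and 11.8). Oas2 and Oas3 did not, with ratios of 0.773 and 0.768 in monocyte-like and 0.847 and 1.43 in macrophage-like cells. Oas1g is not on the interferon response list. A lower interferon response at 2 weeks as the whole cause is argued against by the 20 other interferon genes in monocyte-like cells, whose highest log2 ratio was 1.19 and median −0.05. That highest gene, Cxcl9, was at 2.99 without the 2 cells with most counts, and Oas1a at 8.74. In other classes the interferon list median was 0.41 (macrophage-like), 0.95 (fibroblast-like) and −0.46 (neutrophil-like). A part of the interferon response in the macrophage-like difference is therefore not excluded. Reads moved between Oas1 copies as the whole cause are argued against by the sum of 7 Oas1 genes, still 12.9-fold higher in macrophage-like cells (8.47 to 20.7). In neutrophil-like cells the sum was 5.98-fold higher (3.74 to 9.96), below the 40.6 of Oas1a alone. A variant in all cells of the 2-week library, from donors and recipients alike, is argued against by fibroblast-like cells. Their ratio was 1.73 (1.02 to 3.103) against 14.3 (8.74 to 24.9) in macrophage-like cells, with 17 counts in 7 cells at 2 weeks. These counts were not split by Xist or Y-linked UMIs, so a variant of the recipients alone is not addressed. A variant carried by the recipients, and time after grafting, which is confounded with library, stay open.

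The fibroblast-like share was 3.73-fold higher at 4 weeks. Fewer neutrophil-like cells in the denominator are argued against as the whole cause, since among cells outside that class the share was 6.15% and 19.7%, a ratio of 3.20 (2.38 to 4.37). A different yield from digestion or dissection cannot be told apart from a true difference in the grafts, because endothelial-like cells were 3.26-fold higher as well and each time point is 1 library. Time after grafting is confounded with library and was not tested.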
